A study of Arabidopsis thaliana with 6 samples.

How the data were processed

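Total RNA from whole plants of the Arabidopsis thaliana ceh1 mutant and its parent line was hybridised to 1-colour Affymetrix arrays, 3 biological replicates per genotype and 1 array per replicate. Per the labels' protocols, seeds on 0.5-strength Murashige and Skoog medium were kept 2 days at 4 °C, and plants then grew for 2 weeks at 23 °C, 60% humidity and 100 to 150 µE of light with 8 h of light and 16 h of darkness. Biotinylated cRNA was made from 4 µg of total RNA.

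The deposited values are probe set intensities on a linear scale. Per the submitters' processing notes they were made with MAS5, whose settings and version are not given in the sources used here. The deposited intensities were not at a common level between arrays. Their means, after trimming 2% of the probe sets at each end, differed by up to 1.60-fold, and no detection calls were used here. For arrays, depth in the sense of read counts does not apply, and the number of arrays limits the precision.

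The table held 22810 probe sets. After 64 control probe sets were set aside, 22746 remained, of which 13513 were paired with a single gene in the platform annotation, 503 with several and 8730 with none in the table used. Of the single-gene probe sets, 13436 matched the TAIR10.1 gene table, which was used for names and for the order of genes only. Array coordinates are not printed because the sources used here name no genome build. Unnamed probe sets were tested and counted but not given a gene name. HDS, HPL, ICS1, PR1, BIP3, LOX2 and VSP2, which were to be reported in any case, had no single-gene probe set in that annotation and are not analysed here. BZIP60 had one.

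Values were transformed as log2(intensity + 2), the pseudocount of 2 being the 10th percentile of all values rounded to a whole number, and were quantile normalised. Fold changes are therefore on that scale and understate the change of dim probe sets. Probe sets with a mean below the 30th percentile (log2 3.80) were left out, which kept 15922 probe sets, 8749 of them named and covering 8635 genes. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided), with Benjamini-Hochberg adjustment over the 15922 probe sets and a threshold of 0.05. The design written before the data were examined assumed that MAS5 values were already scaled between arrays and foresaw no further normalization. Quantile normalization, foreseen as an alternative, became the leading setting once the array levels were seen and before any test was run, and the counts without it are given beside the leading ones.

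Gene lists were tested with camera from limma (preset inter-gene correlation 0.01, two-sided, 1 probe set per gene, the brightest), for lists with at least 4 tested members, with Benjamini-Hochberg adjustment over the 30 lists tested. Of the 55 lists, 37 were fixed before the data were examined. Only 94 of the 668 nuclear genes in them were named on the array, so 18 lists were added once the annotation, but no difference between the genotypes, had been seen. The self-test drew 200 changed probe sets among 15922 in 5 runs of simulated arrays. At a log2 fold change of 1, 21.7% were recovered, at 2 76.7%, at 3 82.0% and at 4 93.5%, and 5.19% of calls were false. For camera, simulated lists held 15 genes, and every member of a raised list rose by 1 log2 unit while all other genes stayed unchanged. At an unadjusted p under 0.05, 50 of 50 raised lists and 0 of 50 unchanged ones were called among 8635 genes. Smaller shifts were not simulated, such as the median of 0.14 for cytosolic ribosomal proteins. In both self-tests the simulated probe sets varied independently of each other, and in the first rises and falls were equally many. The share of false calls therefore does not carry over to arrays whose probe sets vary together. Nor could the camera self-test show false calls of lists whose genes vary together.

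Named genes followed a rule fixed before the data were examined. It took the 8 genes listed above, the 8 largest rises and 8 largest falls among named genes past the threshold whose replicates did not overlap between genotypes, the 3 largest passing members of each list past the camera threshold, and the largest passing member of every other list. Genes named beyond this rule, as members counted in a list or as genes that did not pass, were chosen after their values were seen. Signs of RNA quality were compared with an exact two-sided permutation test. Alternatives comprised pseudocounts of 1 and 8, no filter, a filter at the 50th percentile, no normalization between arrays, median scaling, eBayes without a trend, robust eBayes, array weights, a replicate block, an estimated correlation for camera, fry, the mean over a gene's probe sets, each array left out in turn, and, added after the data were seen, a covariate made from 4 evening genes.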

Results

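Transcript levels were measured in whole 2-week-old plants of Arabidopsis thaliana, in the ceh1 mutant and in the parent line from which it derives, with 3 biological replicates per genotype. About 20 plants were collected for RNA. The ceh1 mutation is known to lie in HDS, a plastid enzyme of the methylerythritol phosphate pathway that makes isoprenoid precursors, and the comparison asks how the transcriptome of the mutant differs from that of its parent. HDS itself has no probe set with a single gene name in the annotation used and is not analysed here. Each array carried 22810 probe sets. The trimmed mean intensity was 172.8, 136.7 and 110.7 in parent replicates 1, 2 and 3 and 131.1, 177.1 and 174.3 in ceh1 replicates 1, 2 and 3.

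Plants of the ceh1 mutant carried higher levels of transcripts of the salicylic acid and jasmonate defence responses than the parent, and lower levels of transcripts for proteins of the thylakoid lumen. With an estimated correlation in camera the systemic resistance and thylakoid lists passed, at an adjusted p = 0.0289 and 0.0397, while the other salicylic acid list and both jasmonate lists did not, at an adjusted p = 0.0727. AT5G18470, which encodes a lectin-domain protein, rose from a log2 signal of 1.80 ± 0.66 (SD, n = 3) in the parent to 8.31 ± 0.51 (SD, n = 3) in ceh1. This was the largest rise among named genes, though not in all settings, such as with a pseudocount of 8. AT3G46370, a receptor kinase gene, had the largest fall among named genes and fell by 3.08 on the log2 scale (limma, adjusted p = 0.0463), a call and a rank that did not hold in all settings. Rises were larger than falls, since 122 probe sets rose and 2 fell by at least 8-fold.

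Of 15922 probe sets tested, 600 changed in ceh1 (limma, adjusted p under 0.05). Of these, 417 were higher and 183 lower, so that 69.5% of calls were rises. A change of at least 2-fold was seen in 496 of them, 379 higher and 117 lower. Named single genes made up 301 of the calls, 197 higher and 104 lower, and the other 299 probe sets had no gene or several genes in the annotation used. All 600 had replicates that did not overlap between genotypes, as had 4375 of all tested probe sets, or 27.5%. Chance gives 10% for a single probe set. Probe sets vary together, so the share in any 1 split can differ from that, and the other splits were not compared in this measure. Without normalization between arrays, which shifts the median of all probe sets to 0.21, 718 changed, 657 higher and 61 lower, so that 91.5% of calls were rises, and 416 of them were shared with the 600. All 718 were at least 2-fold, and the adjusted p of AT5G18470 was 1.28e-09, against 0.00079 with quantile normalization (limma). A pass in that fit thus says little about the spread of a gene's replicates. Passes without normalization given below for single genes carry that limit. Array weights gave 1815, 935 higher and 880 lower, so that 51.5% were rises, the replicate block gave 1160, 677 higher and 483 lower, or 58.4% rises, and the filter at the 50th percentile gave 384, 248 higher and 136 lower. The count fell to 168, 152, 296 and 175 without parent replicate 1, parent replicate 2, ceh1 replicate 2 and ceh1 replicate 3, respectively, and was 676 without parent replicate 3.

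CHI (AT2G43570), which encodes a chitinase, rose by a log2 fold change of 6.22 ± 0.46 (SE), and PDF1.2b and THI2.1, which encode an antimicrobial defensin and a thionin, rose by 5.80 ± 0.74 (SE) and 5.64 ± 0.50 (SE). JRG21, which encodes an oxygenase that inactivates jasmonate, rose by 5.77, AT5G52760, a gene for a protein with a heavy-metal-binding domain, by 5.59, and AT3G47480, a gene for a calcium-binding protein, by 5.43. AT2G18690 rose by 5.43 ± 0.30 (SE), with the lowest adjusted p of these genes and AT5G18470 (limma, 0.000518). The probe set of PDF1.2b is of a kind that can also bind transcripts of related genes. In the parent these 8 genes had mean log2 signals between 1.8 and 4.1, near the floor set by the pseudocount, and their order differed between pseudocounts. The rise of AT5G18470 was 7.05 with a pseudocount of 1, above the 6.42 of CHI, and 5.07 with a pseudocount of 8, below the 5.46 of CHI and also below THI2.1. CHI was also above AT5G18470 with the evening-gene covariate and without parent replicate 2 and ceh1 replicate 2, and AT5G18470 was too dim for the filter at the 50th percentile. Each of the 8 rises stayed past the threshold whichever array was left out.

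EXPA8, an expansin gene that acts in cell wall loosening, fell by 2.61 on the log2 scale from 9.61 ± 0.24 (SD, n = 3), and AT3G55710, a glycosyltransferase gene, fell by 2.14. AT4G25780 fell by 2.12, AT5G03130 fell by 2.1, AT3G46490 fell by 2.07, AT3G17640 fell by 2.03 and AT1G69523 fell by 1.95. AT3G46370 did not pass with a pseudocount of 1, without the filter on dim probe sets, without a trend or with robust eBayes (limma, adjusted p = 0.0523, 0.0622, 0.0549 and 0.0513). With a pseudocount of 8 its log2 fold change of −2.37 was smaller than the −2.55 of EXPA8, and without normalization the largest fall was that of BZIP34, at −2.93. Without the filter AT5G03130 did not pass either (limma, adjusted p = 0.0637). EXPA8 and AT3G55710 stayed past the threshold whichever array was left out. The other 6 falls did not, and their highest adjusted p of limma with an array left out was, without parent replicate 2, 0.186 for AT3G46370, 0.130 for AT4G25780, 0.101 for AT3G46490, 0.0679 for AT3G17640 and 0.0713 for AT1G69523, while for AT5G03130 it was 0.173 without parent replicate 1.

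**Figure D1:**
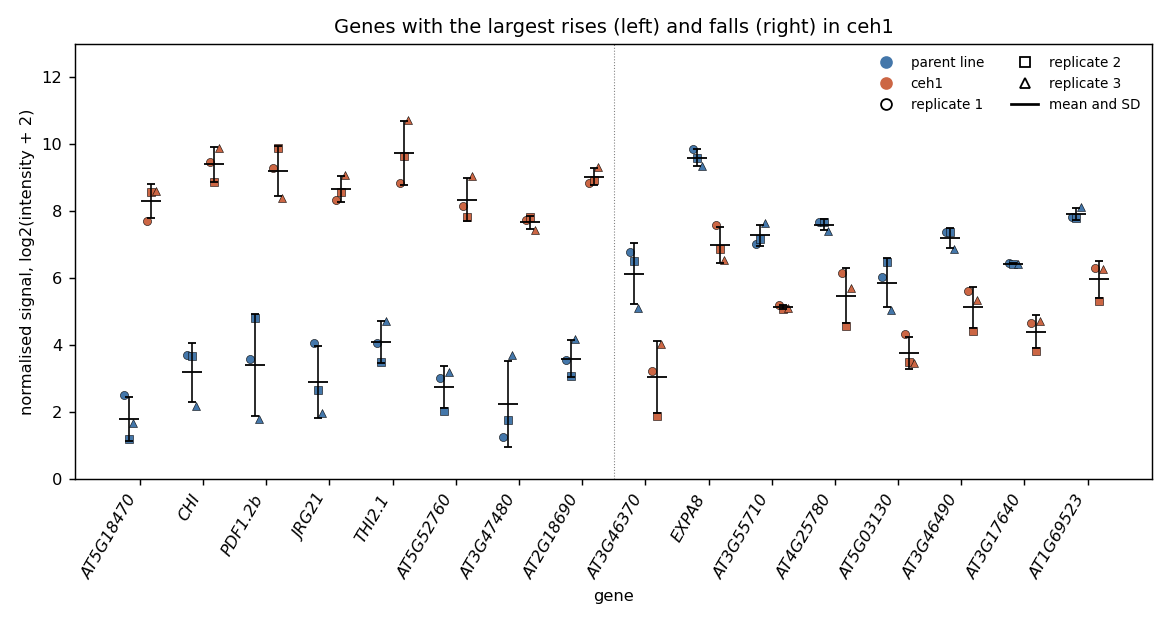
Normalised signal, log2(intensity + 2), of the 8 named genes with the largest rises (left of the dotted line) and the 8 with the largest falls (right) in ceh1, with 1 point per array and bars for the mean and SD of 3 replicates. For each gene the ceh1 and parent points do not overlap, and parent means of the raised genes lie between 1.8 and 4.1.

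Genes of the salicylic acid response rose together. Among 17 tested transcripts known to be induced by salicylic acid or in systemic resistance, 16 rose and 1 did not pass the test, with a median log2 fold change of 3.57 (camera, adjusted p = 1.19e-25, and adjusted p = 0.0289 with an estimated correlation), and 16 rose when adjusted over the list alone. AT5G18470, AT5G52760 and AT3G47480 led this list. In the list for salicylic acid synthesis and response, 3 of 5 tested genes rose over all probe sets and 5 of 5 when adjusted over the list alone, with a median of 1.68 (camera, adjusted p = 6.70e-06, and adjusted p = 0.0727 with an estimated correlation). GRX480, a glutaredoxin that binds TGA transcription factors, rose by 2.31, WRKY6 by 1.68 and SAG101, a partner of EDS1 in immune signalling, by 1.31 ± 0.16 (SE). WRKY53 had a log2 fold change of 2.03 and did not pass the test (limma, adjusted p = 0.156), but passed without normalization (limma, adjusted p = 0.00414), as did AT5G52810, the fifth member (limma, adjusted p = 0.00965). SAG101 stayed past the threshold whichever array was left out, while the highest adjusted p of limma with an array left out was, without parent replicate 2, 0.130 for GRX480 and 0.138 for WRKY6.

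Jasmonate-responsive genes rose as well. In the jasmonate response list, 3 of 4 tested genes rose, and 3 when adjusted over the list alone, with a median of 5.03 (camera, adjusted p = 1.76e-05, and adjusted p = 0.0727 with an estimated correlation). These were PDF1.2b, THI2.1 and PDF1.2, the last by 4.43 ± 0.39 (SE). The probe set of PDF1.2b can also bind transcripts of related genes, so its rise may not be separate from that of PDF1.2. JMT, the jasmonate methyltransferase gene, had a log2 fold change of 0.38 and did not pass (limma, adjusted p = 0.811). Of 8 tested transcripts known to be induced by jasmonate, 7 rose, and 7 when adjusted over the list alone, with a median of 3.14 (camera, adjusted p = 1.77e-12, and adjusted p = 0.0727 with an estimated correlation). JRG21, AT1G54020, a GDSL-type lipase gene, and AT5G05600, a gene for another jasmonate-inactivating oxygenase, rose by 5.77, 5.19 and 3.29. OPCL1, the 1 tested gene of jasmonate synthesis, had a log2 fold change of 0.89 and did not pass (limma, adjusted p = 0.301).

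Lists for the endoplasmic reticulum and for oxidative stress passed camera upwards with its preset correlation, but not with an estimated one. Few of their single genes passed the test. Of 20 tested genes for protein translocation into the endoplasmic reticulum and N-glycosylation, 1 rose over all probe sets and 8 when adjusted over the list alone, with a median of 0.43 (camera, adjusted p = 2.62e-06, and adjusted p = 0.0727 with an estimated correlation). The gene that rose was AT1G29310, which encodes the channel subunit SEC61 alpha, by 1.13 ± 0.19 (SE), and its highest adjusted p with an array left out was 0.115, without parent replicate 1 (limma). AT4G16660 passed as well without normalization and with median scaling (limma, adjusted p = 0.0190 and 0.0485). Of the 6 tested genes of the unfolded protein response, 0 passed over all probe sets and 1, BZIP60, rose when adjusted over the list alone, with a median of 0.37 (camera, adjusted p = 0.0481, and adjusted p = 0.496 with an estimated correlation). The transcription factor gene BZIP60 had a log2 signal of 8.19 ± 0.32 (SD, n = 3) in the parent and 9.13 ± 0.22 (SD, n = 3) in ceh1, a log2 fold change of 0.94 that did not pass (limma, adjusted p = 0.0628). It passed with array weights, with the replicate block and without parent replicate 3, and over all alternatives its adjusted p of limma ran from 0.00822 to 0.233. The list gave 0.0843 without normalization between arrays, 0.129 without parent replicate 1, 0.123 without ceh1 replicate 1 and 0.112 without ceh1 replicate 3 (camera, adjusted p). Its members CRT1b and ATERDJ3B were above all parent arrays in ceh1 replicates 1 and 3 but not in ceh1 replicate 2. CRT1b had log2 signals of 9.07, 9.23 and 9.02 in the parent and 9.97, 8.86 and 9.92 in ceh1. ATERDJ3B had 8.47, 8.48 and 8.60 in the parent and 9.62, 8.54 and 9.63 in ceh1. Of 4 tested genes for oxidative stress and detoxification, 0 passed over all probe sets and 4 rose when adjusted over the list alone, with a median of 1.02 (camera, adjusted p = 0.00082, and adjusted p = 0.0853 with an estimated correlation). They were AT2G21640, CCS, which encodes a copper chaperone, ATMDAR2, which encodes a monodehydroascorbate reductase, and NDB2, with log2 fold changes of 1.35, 1.08, 0.95 and 0.72, and without normalization AT2G21640 and CCS passed over all probe sets (limma, adjusted p = 0.0145 and 0.0285).

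Transcripts for the thylakoid lumen, photosystem assembly and the chloroplast NDH complex fell as a list. Of 32 tested genes, 6 fell over all probe sets and 23 when adjusted over the list alone, 31 had a log2 fold change below 0, and the median was −0.74 (camera, adjusted p = 2.34e-13, and adjusted p = 0.0397 with an estimated correlation). AT1G74070, which encodes a cyclophilin-type protein, fell by 1.2, NdhL, which encodes an NDH subunit, fell by 1.14 ± 0.20 (SE), and AT4G24930, which encodes a lumen protein, fell by 1.01 ± 0.17 (SE). Without normalization between arrays 0 of the 32 genes passed, with a median of −0.51, and with median scaling 11 fell. The highest adjusted p with an array left out was, without parent replicate 1, 0.157 for AT1G74070 and 0.118 for NdhL and, without parent replicate 2, 0.116 for AT4G24930 (limma). The arrays behind these lists also differed in other measures. PYK10, a beta-glucosidase gene of roots and of endoplasmic reticulum bodies, was the 1 tested root marker. It had a log2 fold change of 1.21 and did not pass over all probe sets (limma, adjusted p = 0.0733). With 1 tested gene, adjustment over its list alone leaves the p of limma unadjusted. PYK10 passed in that way, which is no test of the list. The 25S ribosomal RNA signal and the ratio of 3' to 5' actin signal differed by 1.95 and −0.28 in log2, with replicates that did not overlap (exact two-sided permutation test, p = 0.1 for each).

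Medians for plastid ribosomal proteins, the plastid genome, light harvesting, the Calvin cycle and chlorophyll synthesis were below 0, apart from that for chlorophyll synthesis without normalization, and lay further below 0 with median scaling. Of 10 tested nuclear genes for plastid ribosomal proteins, 0 passed over all probe sets and 2, AT4G17560 and AT5G47190, fell when adjusted over the list alone, with a median of −0.32 (camera, adjusted p = 0.00556, and adjusted p = 0.202 with an estimated correlation). With median scaling that median was −0.53 and AT4G17560 passed over all probe sets. Of 69 genes of the plastid genome, 0 passed, with a median of −0.18 (camera, adjusted p = 0.00146, and adjusted p = 0.496 with an estimated correlation), and with median scaling the median was −0.40 (camera, adjusted p = 4.14e-10). The 112 genes for cytosolic ribosomal proteins had 0 passing members and a median of 0.14 (camera, adjusted p = 0.000411, and adjusted p = 0.564 with an estimated correlation), and the adjusted p was 0.287 without normalization, 0.222 with median scaling and 0.165 without parent replicate 3. All 8 tested light-harvesting and photosystem genes had log2 fold changes below 0, from −0.49 for PSBY to −0.09 for PSAE-1, and 0 passed, with a median of −0.20 (camera, adjusted p = 0.0829, and adjusted p = 0.422 with an estimated correlation). That list gave an adjusted p of 0.0293 with fry, and of camera 0.0457 with the filter at the 50th percentile, 0.00648 without normalization and 0.000336 with median scaling, where the median was −0.53 and PSBY passed. The 3 tested genes of the Calvin cycle, too few for camera, were RCA, PRK and SBPASE, with log2 fold changes of −0.22, −0.37 and −0.79. None of them passed over all probe sets, 2, PRK and SBPASE, fell when adjusted over the list alone, and with median scaling the median was −0.68 and PRK passed. For chlorophyll synthesis the median of 5 genes was −0.13, 0.03 without normalization and −0.23 with median scaling (camera, adjusted p = 0.340). The 13 genes of the mitochondrial genome had a median of 0.06, and 0.31 without normalization (camera, adjusted p = 0.151). That list gave 0.0136 with the filter at the 50th percentile, 0.0468 with array weights and 0.0481 without parent replicate 3 (camera, adjusted p), against an adjusted p = 0.496 with an estimated correlation and 0.223 with fry. The signal of the 25S ribosomal RNA control probe set was 416.9, 985.4 and 293.7 in the parent and 1343, 4598 and 1132 in ceh1, a difference of 1.95 in log2 (exact two-sided permutation test, p = 0.1, the smallest that 3 against 3 arrays allow).

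**Figure D2:**
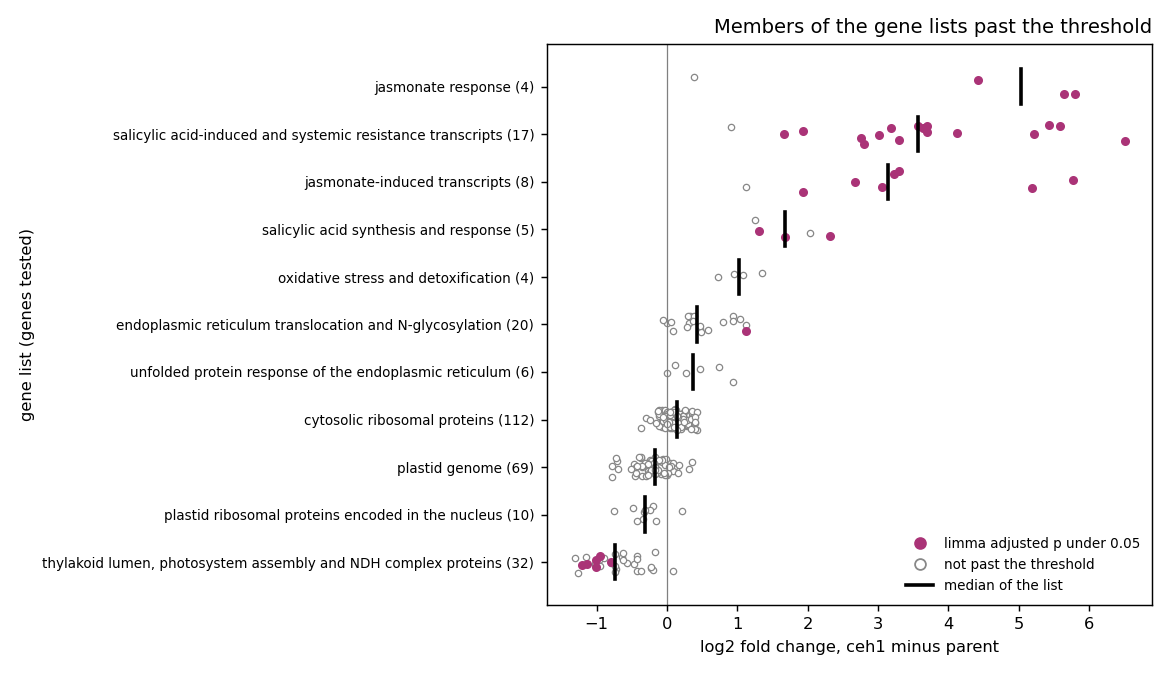
Log2 fold change, ceh1 minus parent, of each tested gene in the 11 lists past the camera threshold, with filled points for genes past the limma threshold, open points for the others and a bar at the list's median. Medians run from −0.74 for the thylakoid list to 5.03 for jasmonate response.

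Single members of other lists changed while the lists did not pass. XTH18, a xyloglucan endotransglucosylase gene, rose by 2.89 ± 0.37 (SE) in a list of 5 with a median of 0.87 (camera, adjusted p = 0.0629), and EXPA8 was the 1 gene that fell among 12 expansins with a median of −0.54 (camera, adjusted p = 0.0542) and 1 of 3 tested genes for cell wall expansion. Among 42 TIR-domain immune receptor genes, AT1G57630 and AT2G20142 rose, by 4.65 and 3.97, and AT5G46270 fell by 0.84, the last 2 of these chosen after their values were seen. Without normalization 3 rose, AT1G72900 being the third, and AT5G46270 did not pass. That list had a mean of 0.22 and a median of −0.08, which was 0.15 without normalization (camera, adjusted p = 0.801). BGLU25 rose by 1.66 and BGLU33, chosen after its value was seen, fell by 1.06, though not past the threshold without normalization, among 10 beta-glucosidases (camera, adjusted p = 0.216). UGT87A2 rose by 1.42 among 27 glycosyltransferases, whose median was −0.03, and 0.24 without normalization (camera, adjusted p = 0.397), and TBL37 by 1.52 among 15 wall acetylation genes (camera, adjusted p = 0.811). GH3.3, an auxin-conjugating enzyme gene, rose by 2.21 among 4 auxin genes with a median of −0.17, and 0.09 without normalization (camera, direction up, adjusted p = 0.896). AT2G04400, which encodes indole-3-glycerol phosphate synthase of tryptophan synthesis, rose by 1.13. AT3G46370 was the 1 faller among 7 malectin-like receptor kinases, whose median was 1.31 (camera, adjusted p = 0.255), while AT1G51790, AT1G51890, AT3G46280 and AT5G59670 rose when adjusted over the list alone and, without normalization, over all probe sets (limma, adjusted p = 0.0375, 0.00714, 0.00369 and 0.0237). Without normalization XTH19 and EXLB1 passed as well, with log2 fold changes of 3.26 and −1.29. The expansin list passed without parent replicate 2, parent replicate 3, ceh1 replicate 1 and ceh1 replicate 3, at 0.0299, 0.0439, 0.0164 and 0.0314, and also without normalization, with a pseudocount of 8, with no filter, with the filter at the 50th percentile and with the replicate block, at 0.0018, 0.0486, 0.0201, 0.0367 and 0.0368 (camera, adjusted p). The list of XTH18 passed without parent replicate 1, parent replicate 2 and ceh1 replicate 2, at 0.0187, 0.0420 and 0.00394, and also without normalization, with no filter, with the replicate block and with the evening-gene covariate, at 0.00505, 0.0462, 0.0392 and 0.0107 (camera, adjusted p). With an estimated correlation neither passed, the expansins at an adjusted p = 0.496. GH3.3 lost its call whichever array was left out. The highest adjusted p with an array left out was, without parent replicate 2, 0.0561 for XTH18, 0.0659 for UGT87A2 and 0.135 for GH3.3, without ceh1 replicate 3 it was 0.0711 for TBL37, and without parent replicate 1 it was 0.139 for AT2G04400 (limma).

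In all, 11 of 30 tested lists passed camera with its preset correlation, 5 of them fixed before the data were examined and 6 once the annotation had been seen, and 2 passed with an estimated correlation, the systemic resistance and thylakoid lists. Another split of the 6 arrays, with parent replicates 1 and 3 and ceh1 replicate 2 on one side, gave 11 lists as well.

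Arrays of one genotype differed in genes with a daily rhythm. The clock gene GI had log2 signals of 7.52, 7.49 and 9.56 in parent replicates 1, 2 and 3 and of 7.66, 8.98 and 8.60 in ceh1 replicates 1, 2 and 3. COR27, another evening gene, had 3.07, 1.70 and 9.75 in the parent and 1.80, 9.10 and 9.69 in ceh1. GI and COR27 did not pass the test between genotypes (limma, adjusted p = 0.873 and 0.716). Parent replicate 3 correlated with the mean of the other parent arrays at 0.930 across probe sets, against 0.973 and 0.969 for parent replicates 1 and 2. The log2 ratio of 3' to 5' signal was 4.34 ± 0.10 (SD, n = 3) for actin in the parent and 4.06 ± 0.06 (SD, n = 3) in ceh1, with an exact permutation p = 0.1, 1.70 and 1.48 for ubiquitin, with an exact p = 0.1, and 0.59 and 0.61 for GAPDH, with an exact p = 0.9. Over the 5 array measures compared in this way the lowest Benjamini-Hochberg adjusted value was 0.167.

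**Figure D3:**
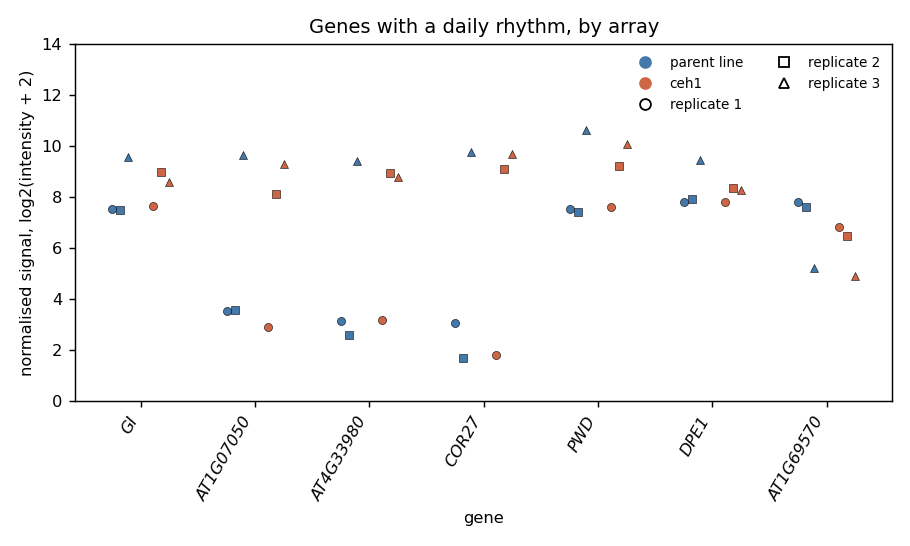
Normalised signal, log2(intensity + 2), of 7 genes with a daily rhythm, with 1 point per array. GI was at 9.56 in parent replicate 3 and at 8.98 and 8.60 in ceh1 replicates 2 and 3, against 7.49 to 7.66 in the other arrays.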

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

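All settings but the covariate made from evening genes were listed before the data were seen, and quantile normalization was moved from alternative to leading setting once the array levels were seen. No result past the threshold in the leading setting or in the alternative changed direction between them. Among the 30 lists tested with camera, 7 medians, none of a list past the threshold, changed sign without normalization. Medians of some lists too small for camera, such as the mevalonate pathway, changed sign as well. The 600 changed, 417 higher, 183 lower and 496 at least 2-fold changed probe sets became 384, 248 and, at least 2-fold, 301 with the filter at the 50th percentile, where fewer probe sets were tested. Without normalization between arrays 657 were higher and 61 lower. Array weights gave 1815, 935, 880 and 1029, the replicate block 1160, 677, 483 and 877, and the evening-gene covariate 297 lower. The cause of these moves was not tested. The replicate numbers were not taken to pair arrays, because the labels do not say that they mark a shared day or batch. Same-numbered arrays correlated at 0.27, 0.06 and 0.47 in their deviations from the group means, and 2 of 3 arrays in each genotype correlated best with their own number. These values do not exclude pairing, so whether the arrays are paired stays open. With an array left out, so fewer samples, changed probe sets ran from 152 (without parent replicate 2) to 676 (without parent replicate 3), higher from 146 to 495, lower from 6 to 181 and at least 2-fold from 152 to 633.

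Of 11 lists, 2 passed camera with an estimated correlation. Adjusted p was then 0.0727 for salicylic acid synthesis and response, jasmonate response, jasmonate-induced transcripts and endoplasmic reticulum translocation, 0.0853 for oxidative stress, 0.496 for the unfolded protein response and the plastid genome, 0.564 for cytosolic and 0.202 for plastid ribosomal proteins. With fry it was 0.144 for the unfolded protein response, 0.133 for the plastid genome and 0.338 for cytosolic ribosomal proteins. The unfolded protein response had 0.0843 without normalization and 0.0546 without a trend, and 0.00077 to 0.129 with an array left out. Cytosolic ribosomal proteins had 0.287 without normalization, 0.222 with median scaling, and 2.06e-07 to 0.165 with an array left out. Of 33 named genes past the threshold, 16 kept their call whichever array was left out, and 17, 17, 2, 8, 9 and 13 lost it without parent replicates 1, 2 and 3 and ceh1 replicates 1, 2 and 3. Other settings ended the calls of AT1G74070, NdhL and AT4G24930 without normalization (limma, adjusted p = 0.149, 0.124 and 0.333), of AT3G46370, AT2G04400, GH3.3 and AT1G74070 without a trend (0.0549, 0.0505, 0.0518 and 0.0539), of AT3G46370, AT5G03130 and WRKY6 with no filter (0.0622, 0.0637 and 0.0535), and of AT3G46370 with a pseudocount of 1 (0.0523) and robust eBayes (0.0513). BZIP60, not called in the leading setting, passed with array weights, with the replicate block and without parent replicate 3. Dim probe sets limit the largest folds, which shrink with a higher pseudocount.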

Other observations

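The tests of the evening genes were chosen after the pattern was seen, as was the count of neighbouring pairs with a marked probe set. The other tests of neighbouring genes and of other splits were chosen before their results were seen.

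Some stress genes outside the lists past the threshold varied between parent arrays, as did WRKY53 inside the list for salicylic acid synthesis and response. STZ and CML38, both rapidly induced by many stresses, had log2 fold changes of 1.97 and 2.06 and did not pass (limma, adjusted p = 0.240 and 0.146), though both passed without normalization (limma, adjusted p = 0.0237 and 0.00421). Those passes do not show a difference beyond the spread of the parent arrays. Parent replicate 3 stood apart from the other parent arrays and overlapped ceh1. STZ had log2 signals of 6.23, 5.97 and 9.47 in the parent and 8.96, 9.15 and 9.47 in ceh1, and CML38 had 5.60, 5.44 and 8.02 in the parent and 8.18, 7.98 and 9.08 in ceh1. The immune signalling gene BIK1 had a log2 fold change of 0.84 and did not pass (limma, adjusted p = 0.116). The reference genes had a median of −0.04, and 0.07 without normalization, with 0 of 4 past the threshold.

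The remaining tested lists did not pass. Adjusted p of camera was 0.271 for 4 heat shock genes, 0.772 for 7 small and 70-kDa heat shock genes, 0.401 for 5 flavonoid genes, 0.186 for 8 autophagy genes, 0.173 for 6 tau glutathione transferases, 0.401 for 8 SWEET transporters and 0.812 for 7 MADS-box genes, whose median of 0.17 and mean of −0.16 differed in sign. The flavonoid list depended on single arrays, with 0.00458 without ceh1 replicate 2 and 0.934 without parent replicate 3 (camera, adjusted p), against an adjusted p = 0.797 with an estimated correlation. Among probe sets without a gene in the annotation used, the largest rise was a log2 fold change of 8.68, from a parent mean log2 signal of 2.25 near the floor set by the pseudocount, and the largest fall was −3.43.

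Raised genes lay next to each other along the chromosomes in 5 of 2985 neighbouring pairs in which both genes were measured, where 10000 shuffles of the calls averaged 1.58 (permutation test, one-sided, p = 0.0237). AT5G52740, AT5G52750 and AT5G52760 formed 2 of these pairs, and AT5G64110 with AT5G64120, both peroxidase genes, another. Probe sets marked as shared between copies are argued against as the source, since 0 of the 5 pairs had a gene measured by one. Leaving them out, which kept 193 of 195 raised genes, therefore had to leave the count at 5. The highest of the shuffles was then 7 (permutation test, one-sided, p = 0.0193), which is no further support. Probe sets without that mark could also bind transcripts of a neighbouring copy, so this source stays open, the count of 5 lying between the bounds set in advance, and whether neighbouring copies respond alike was not tested.

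The 4 named evening genes GI, COR27, AT1G07050 and AT4G33980 had the same 3 arrays highest, parent replicate 3 and ceh1 replicates 2 and 3. A dim array as the source is argued against by the trimmed mean of 177.1 in ceh1 replicate 2, above the 172.8 of the brightest other array. Chilling of the plants stays open, since COR15A, COR15B and COR47 differed between ceh1 replicates 2 and 1 by a median of 0.0343 in log2 with members going both ways. Across all arrays these genes differed more, and each was highest in parent replicate 3 and next in ceh1 replicate 3. COR15B had log2 signals of 6.16, 6.22 and 11.70 in the parent and 7.89, 7.93 and 10.59 in ceh1. COR15A had 7.36, 8.16 and 11.49 in the parent and 9.92, 8.94 and 11.02 in ceh1. A different time of day at harvest is a candidate explanation, since PWD and DPE1 of starch breakdown and the morning gene AT1G69570 had the same 3 arrays at the predicted end, 3 of 3, but the values of 2 of these had been seen when the genes were listed, and 1 gene decides nothing. Genotype, the biological difference in the design, does not separate these arrays, since 1 is of the parent and 2 are of ceh1, and chilling and time of day are states of the plants that the labels do not give for each array.

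There were 10 splits of the 6 arrays, too few for a share under 0.05. The real split gave 600 changed probe sets and the highest other 104. With the real split included, 1 of the 10 splits gave as many, so no other split did. For probe sets on the side with more calls these values were 417, 63 and 1, on the other side 183, 41 and 1, and for changes of at least 2-fold 496, 102 and 1. The highest other split set parent replicates 1 and 2 and ceh1 replicate 1 against the arrays with raised evening genes. For lists past the camera threshold the real split gave 11 and the highest other 11, so 2 of 10 splits gave as many, the real one included.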
